A study of Arabidopsis thaliana with 18 samples.

How the data were processed

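Shoots and roots of Arabidopsis thaliana ecotype Ws-2 were compared between control, potassium-starved and caesium-treated plants, with 3 Affymetrix ATH1 arrays in each of 6 groups. Per the labels, total RNA was extracted, labelled cRNA was made from a primer with a T7 promoter and an oligo-dT stretch, and each array was hybridised with 1 sample. The deposited values are signal intensities on a linear scale, background-corrected and scaled by the authors so that the mean of each array without the outer 2% of values at either end is about 100. The software is not given in the sources used here, and detection calls were not used here. Each array held 22810 probe sets, of which 64 were controls. The 18 arrays are the only depth there is, and their number limits the precision. The titles of 2 root arrays, potassium-starved replicate 1 and caesium-treated replicate 2, are marked as repeats.

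Intensities were transformed as log2 of the value plus 16, without further scaling between arrays. Within each organ, probe sets whose mean lay above the 40th percentile were tested, a floor at a signal of 26.7 in shoots and 27.7 in roots, which left 13647 in each organ. A log2 change from or to a group mean below the floor depends on the 16 added and is no exact size. Linear models with moderated variances were fitted to the 9 arrays of an organ with limma 3.58.1 in R 4.3.3, and p-values, all two-sided, were adjusted by the Benjamini-Hochberg method in each comparison, with a threshold of 0.05. Every adjusted p of a gene comes from limma, and every adjusted p of a list from limma's camera. The comparisons were potassium-starved against control, caesium-treated against control and caesium-treated against potassium-starved plants in each organ. The differences between root and shoot responses were tested as interaction terms over the 18 arrays and the 11867 probe sets above the floor in both organs. Measures of array quality were compared by exact permutation tests, whose smallest two-sided p with 3 against 3 arrays is 0.1.

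Probe sets were named from the annotation tables used here: 13513 matched 1 gene, 503 several and 8730 were not listed, so that 7355 of the probe sets tested in shoots and 7405 of those in roots carried a gene name. A panel of 12 genes chosen before the data were examined had 0 members with a named probe set, so it was not analysed here. The tested probe sets without a name are in the counts only.

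Before the data were examined, 29 lists of pathway genes and markers were fixed, with 475 members, of which 61 had a named probe set. These were 5 of 26 for photosynthesis, 3 of 15 for senescence, 5 of 19 for oxidative stress and 4 of 20 for the abscisic acid, drought and cold response. Potassium transporters and channels had 1 of 25 and low-potassium signalling 0 of 13. Members called measured below are those named and tested, and the others were not assessed. A further 30 gene families were listed after the probe table was seen and before any test, and the pattern of 1 of these, cytochromes P450, was corrected after a first run because it had caught 2 other genes by symbol. Lists with at least 5 tested members were compared with other genes by camera with a preset correlation of 0.01, and again with a correlation estimated from the data, under which 0 of 36 calls remained. Cytochromes P450 gave no camera call in any comparison without the replicate number as a block.

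Genes were named by a rule fixed before the data were examined. For each comparison with control these were the 7 largest rises and 7 largest falls past the threshold whose groups did not overlap, and for the other comparisons 6 each way. To these came up to 3 members, or 2 in the other comparisons, of each list with at least 2 members past the threshold, and where fewer than 5 genes passed, the 5 with the smallest p. After results were seen, the part on lists was extended to the added families, only where a family had a camera call in the comparison. Genes named outside the rule are said to be so.

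Whether replicate numbers pair the samples was decided by a fixed rule, that the deviations of arrays with the same number correlate by more than 0.1 for every number. This held in shoots for all 3 comparisons (lowest r 0.319, 0.495 and 0.207) and in roots for caesium against control (lowest r 0.180), but not in roots for potassium starvation against control (-0.0299) or caesium against potassium starvation (0.0864). Taken over all pairs of root arrays together the rule would not have held. Where it held, values with the replicate number as a block stand beside the result when they change it.

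The pipeline was tested on simulated data with the spread of these arrays. Of 100 probe sets given a log2 change of 1, 48 were found in shoots and 66 in roots, and of 100 with a change of 2, 96 and 93, with 7 and 4 false calls among 13647. With no change simulated there were 0 calls. For the responses that share control arrays, 100 sets of unchanged groups with the same controls were simulated. They gave the correlation and covariance that sharing alone produces with no real change and no pairing by replicate number. For signs and overlaps in shoots a further 100 sets, added after the result was seen, took as many probe sets as were called, by moderated t.

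Alternatives planned before the data were examined were a pseudocount of 1 or 64, quantile normalization, centring each array on its median, no filter or a filter at the 60th percentile, the replicate number as a block, all 18 arrays or only the 2 groups compared in the model, array weights, the scanner background as a covariate, a trended and robust variance model, no moderation, a minimum of a 2-fold change, a threshold of 0.1, and leaving out each array in turn. After seeing the data, 3 were added: the signal of the 25S ribosomal RNA control probe set as a covariate, leaving out the 2 root arrays titled as repeats, and leaving out the 2 caesium-treated root arrays with a high 25S signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and statmod 1.5.0 was used by limma.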

Results

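Transcript levels were measured in shoots and roots of Arabidopsis thaliana ecotype Ws-2 under 3 nutrient treatments. Control plants grew on dilute Murashige and Skoog medium, potassium-starved plants on the same medium without potassium, and caesium-treated plants on the medium with 2 mM caesium, an alkali metal ion that competes with potassium for uptake. Each of the 6 groups of organ and treatment held 3 samples. Each sample pooled 40 to 50 plants and was hybridised to 1 Affymetrix ATH1 array, which gave 18 arrays with signals for 22746 probe sets other than controls. The labels number the samples 1 to 3 as replicates but do not say whether they came from separate sowings, so p-values measure the spread between these samples.

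The median signal of an array lay between 33.0 and 45.4, while the highest signals reached between 3722 and 6513. Across probe sets, which are not independent replicates, arrays of 1 group correlated with r between 0.956 and 0.985, arrays of different treatments of the same organ with r between 0.886 and 0.980, and arrays of different organs with r between 0.683 and 0.779. Genes of photosynthesis separated the organs: the signal of PRK, a Calvin cycle kinase, lay between 641 and 2441 on the shoot arrays and between 12.4 and 32.1 on the root arrays. PYK10, a beta-glucosidase abundant in roots, lay between 1915 and 3501 on the root arrays and between 46.9 and 1200 on the shoot arrays. In shoots, the first principal component held 52.8% of the variance and placed the potassium-starved arrays at 31.1 to 64.2 and all control and caesium-treated arrays at -35.8 to -13. In roots, the first component held 34.3% and placed the potassium-starved arrays at 13.4 to 33.1 and the others at -29.8 to -0.189.

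Potassium starvation of shoots raised the transcripts of CML41, AMY1 and SAG29 and lowered that of BZIP61, and all 4 also passed without any 1 array. CML41, a calmodulin-like protein, rose from a signal of 39.1 ± 17.7 in control shoots to 1122 ± 217 in potassium-starved shoots (SD, n = 3 per group), a log2 change of 4.39 ± 0.31 (SE) at a limma adjusted p of 2.3e-05. AMY1, an alpha-amylase, rose from 29.3 ± 4.10 to 825 ± 328 (SD, n = 3), a log2 change of 4.15 ± 0.25 at an adjusted p of 1.2e-05. SAG29, a SWEET family sugar transporter of senescing leaves, rose from 7.43 ± 2.22 to 327 ± 107 (SD, n = 3), a log2 change of 3.83 ± 0.45 at an adjusted p of 0.000314. BZIP61, a bZIP transcription factor, fell from 121 ± 6.86 to 8.37 ± 7.49 (SD, n = 3), a log2 change of -2.53 ± 0.25 at an adjusted p of 0.000121. The low groups of SAG29 and BZIP61 lay below the floor of 26.7, so the sizes depend on the added 16. With a pseudocount of 1 and 64 they were 5.26 and 2.42 for SAG29 and -3.98 and -1.36 for BZIP61, and both passed.

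The other largest rises in potassium-starved shoots were those of AT4G18280 (log2 change 4.24 ± 0.19), AT1G05340 (3.88 ± 0.39), AT2G32190 (3.79 ± 0.47) and AT1G58420 (3.68 ± 0.20), with adjusted p between 2.6e-06 and 0.000422. The other largest falls were those of AT4G23820 (-2.34 ± 0.23), SKU5 (-2.30 ± 0.19), AT5G12050 (-2.28 ± 0.32), AT5G62280 (-2.24 ± 0.54), AT1G04040 (-2.23 ± 0.29) and AT5G16030 (-2.23 ± 0.34), with adjusted p between 5.0e-05 and 0.0119. In each of these genes all 3 potassium-starved arrays lay on 1 side of the 3 control arrays, as the rule for naming them required. AT2G32190 in control shoots and AT5G62280 in potassium-starved shoots had means below the floor, so that their sizes also depend on the pseudocount.

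Among the lists of genes fixed before the data were examined, photosynthesis had 5 measured genes of 26 listed. Of these 5, 4 fell in potassium-starved shoots and none rose, both over all probe sets and adjusted over the list alone. SBPASE, a Calvin cycle phosphatase, fell from 1701 ± 157 to 899 ± 295, PRK from 2197 ± 251 to 1218 ± 518, and LHCB4.2, a light-harvesting protein of photosystem II, from 1973 ± 682 to 991 ± 140 (SD, n = 3). Their log2 changes were -0.96 ± 0.23, -0.94 ± 0.29 and -0.94 ± 0.29, and adjusted p was 0.0124, 0.0305 and 0.0351. The set test of this list did not pass (camera adjusted p = 0.0619). Without control shoot replicates 1, 2 and 3 and potassium-starved shoot replicates 1, 2 and 3 in turn, 1, 2, 2, 3, 2 and 3 of the 5 fell. LHCB4.2 passed only without control shoot replicate 3 (0.0469; up to 0.103 otherwise), and PRK did not without control shoot replicate 1 or 3 (up to 0.0931). All 3 measured genes of senescence rose, also adjusted over the list alone. Beside SAG29 these were the transcription factors WRKY6 (log2 change 1.65 ± 0.25, adjusted p = 0.00117) and WRKY53 (1.26 ± 0.34, adjusted p = 0.0184), WRKY6 from a control mean below the floor. WRKY53 was the only one lost without 1 array, control shoot replicate 3 or potassium-starved shoot replicate 1. Of 4 genes of the abscisic acid, drought and cold response, 3 rose and 1 fell, counts that were the same adjusted over the list alone. LTI30, a dehydrin, rose by 2.99 ± 0.44 on the log2 scale and COR15A, a chloroplast protein of the cold response, by 1.96 ± 0.57, while COR15B fell by 0.99 ± 0.22. In the same 6 fits 1, 1, 3, 2, 1 and 2 of these rose and COR15B always fell.

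Among genes of oxidative stress 4 of 5 rose in potassium-starved shoots, and also 4 of 5 adjusted over the list alone. NDB2, an external NAD(P)H dehydrogenase of mitochondria, rose from 77.5 ± 9.48 to 456 ± 121 (SD, n = 3; log2 change 2.31 ± 0.21, adjusted p = 9.0e-05). STZ, a zinc finger protein, rose by 1.32 ± 0.34 (adjusted p = 0.0160), and ATMDAR2, a monodehydroascorbate reductase, by 0.92 ± 0.21 (adjusted p = 0.00937). In the same 6 fits 2, 3, 2, 2, 2 and 4 of the 5 rose, NDB2 in each. Camera placed this list above other genes at an adjusted p of 0.0199, or an adjusted p = 0.668 with an estimated correlation. Cell wall expansion genes went both ways, 3 up and 1 down of 4, also adjusted over the list alone. XTH19, a xyloglucan endotransglucosylase, rose by 1.87 ± 0.25 and EXLA1, an expansin-like protein, by 1.77 ± 0.32, while the expansin EXPA8 fell by 1.45 ± 0.31. Of 2 measured members of the list of cyclic nucleotide-gated and glutamate receptor-like channels, ATGLR1.2 rose by 0.53 ± 0.17 (adjusted p = 0.0368, but 0.0774 with a pseudocount of 64, its control mean being below the floor) and GLR3.3 fell by 0.63 ± 0.18 (adjusted p = 0.0222), each also adjusted over the list alone.

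Of 67 plastid-encoded genes, 18 fell and none rose in potassium-starved shoots, with the median of all 67 at -0.55 on the log2 scale. The genes of the ATP synthase subunits atpF and atpA fell by 1.58 ± 0.26 and 1.42 ± 0.28, and psaA, a core protein of photosystem I, fell by 2.21 ± 0.40, with adjusted p of 0.00181, 0.00425 and 0.00302. Camera placed the list below other genes at an adjusted p of 0.00138, which became an adjusted p = 0.792 with an estimated correlation. Mitochondrion-encoded genes went the other way, with 4 of 12 up and none down. Among them were nad1 (0.90 ± 0.18), cox2 (0.64 ± 0.20) and ccb206 (0.60 ± 0.19). Camera gave an adjusted p of 0.0316, or an adjusted p = 0.792 with an estimated correlation. Autophagy genes rose, 4 of 8, with the ubiquitin-like ATG8D at 1.37 ± 0.18, ATG8B at 1.25 ± 0.26 and ATG8G at 0.65 ± 0.14. Camera gave an adjusted p of 0.0103, an adjusted p = 0.668 with an estimated correlation and 0.0499 without potassium-starved shoot replicate 2. Mean log2 values of the family, relative to all shoot arrays, were 0.16, 0.85 and 0.18 on the potassium-starved arrays and -0.14, -0.24 and -0.41 on the control arrays.

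Further families passed camera in potassium-starved shoots, each with adjusted p = 0.668 or higher with an estimated correlation. WRKY transcription factors had 4 rises and 1 fall among 5, with WRKY47 at 1.29 ± 0.18 and WRKY20 at -0.69 ± 0.18 (camera adjusted p = 0.0316). Ubiquitin-conjugating enzymes had 4 rises among 10, with UBC30 at 0.88 ± 0.17, UBC27 at 0.80 ± 0.17 and UBC29 at 0.67 ± 0.16 (adjusted p = 0.0316, but 0.0560 after quantile normalization). Cytosolic ribosomal protein genes had 5 rises among 59, a smaller share than the 1645 rises among all 13647 tested probe sets. Among them were AT5G39850 at 1.01 ± 0.18, AT4G25740 at 0.78 ± 0.16 and AT5G67510 at 0.74 ± 0.21. The camera adjusted p of this family, 0.0265, was 0.412 after quantile normalization. With the replicate number as a block, which pairs these samples, calmodulin-like genes also passed (adjusted p = 0.0400, against 0.0619 without it and adjusted p = 0.668 with an estimated correlation). Without potassium-starved shoot replicate 2 the camera adjusted p was 0.167 for the ribosomal proteins and the ubiquitin-conjugating enzymes and 0.0537 for the WRKY factors and the mitochondrion-encoded genes. Without control shoot replicate 1 it was 0.233 for the ribosomal proteins and 0.0541 for the ubiquitin-conjugating enzymes, and without control shoot replicate 2 it was 0.0550 for these enzymes and the WRKY factors and 0.107 for the mitochondrion-encoded genes.

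**Figure D1:**
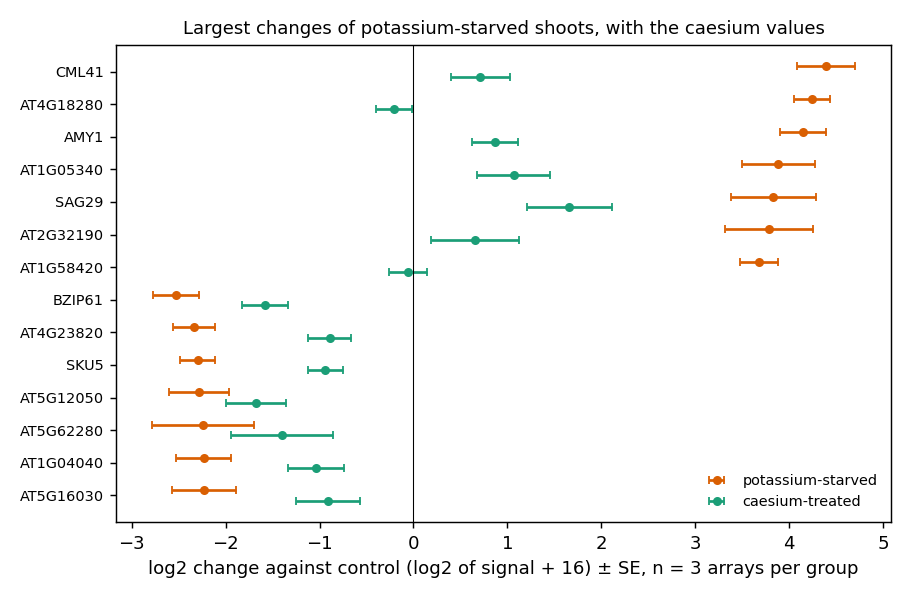
Log2 change against control shoots (horizontal axis, log2 of signal + 16) of the 7 largest rises and 7 largest falls of potassium-starved shoots, in orange, with the caesium values of the same genes in green. Points are limma estimates with SE from 3 arrays per group; CML41 stood at 4.39 under potassium starvation, and the caesium points of the falls lay below 0.

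In all, 3983 of 13647 probe sets changed in potassium-starved shoots by limma at an adjusted p under 0.05, 1645 up and 2338 down, and 1480 of them by 2-fold or more. The median log2 change of all tested probe sets was -0.12 with the authors' scaling, and relative to it, with each array centred on its median, 2010 rose and 1767 fell. The number of arrays limits the precision. Of 47 named genes 35 passed in all 6 fits without 1 array, and the other 12 did not, with an adjusted p up to 0.114. Like the main model, these fits left out the pairing by replicate number. LHCB4.2 and ccb206 passed in 1 of the 6 fits, and ATGLR1.2, COR15A, STZ and cox2 in 2. GLR3.3, AT5G67510 and WRKY20 passed in 3, PRK and WRKY53 in 4 and UBC29 in 5. Without control shoot replicate 3 the count was 2372, and without control shoot replicate 1 it was 2507.

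In roots, potassium starvation raised AT3G12900 the most, from 139 ± 39.9 in control roots to 965 ± 36.7 in potassium-starved roots (SD, n = 3), a log2 change of 2.70 ± 0.17 at a limma adjusted p of 8.5e-05. ASPGB1, an asparaginase, rose from 179 ± 49.9 to 636 ± 137 (SD, n = 3), a log2 change of 1.75 ± 0.22 at an adjusted p of 0.00615. AT3G61930 rose by 1.82 ± 0.18, AT4G22610 by 1.65 ± 0.23, AT4G33666 by 1.57 ± 0.16, AT2G41730 by 1.55 ± 0.28 and AT5G38910 by 1.51 ± 0.29, with adjusted p between 0.00249 and 0.0362. The largest fall was that of AT1G14960, from 273 ± 38.3 to 83.7 ± 24.5 (SD, n = 3; log2 change -1.56 ± 0.19, adjusted p = 0.00615). It was followed by AT1G73600 (-1.44 ± 0.18), AT3G57010 (-1.33 ± 0.26), AT2G19060 (-1.22 ± 0.21), AT3G05900 (-1.22 ± 0.18), AT5G62360 (-1.05 ± 0.20) and XTH19 (-1.05 ± 0.20), with adjusted p up to 0.0363. The control mean of AT2G41730 and the potassium-starved mean of AT5G62360 lay below the floor of 27.7.

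Of 6 measured genes of cell wall expansion in roots, XTH19 fell and the expansin EXPA4 rose, by 0.74 ± 0.15 (adjusted p = 0.0450); adjusted over the list alone, 1 rose and 2 fell. Extensins, the trichome birefringence-like family and xyloglucan endotransglucosylases lay below other genes as sets in potassium-starved roots, each with an adjusted p = 0.513 with an estimated correlation. The 12 tested expansins did not (median 0.01, camera adjusted p = 0.920). Root hair markers in control and potassium-starved roots stood at 116 ± 23.2 and 74.2 ± 4.47 for EXPA18, 66.6 ± 3.76 and 62.8 ± 12.9 for EXPA7 and, below the floor, 19.8 ± 13.9 and 4.3 ± 2.57 for XTH26 (SD, n = 3). AT3G49960 stood at 31.5, 210 and 25.7 on the control arrays against 24.9 ± 7.95, so a lower mean rests on control root replicate 2. None of the 3 tested passed over all probe sets, and EXPA18 was lower adjusted over the list alone. Extensins, structural glycoproteins of the wall, had 0 of 9 members past the threshold over all probe sets and 5 lower adjusted over the list alone, with a median of -0.61 (camera adjusted p = 0.0180; adjusted p = 0.513 with an estimated correlation). The trichome birefringence-like family of wall acetylation had 1 fall among 16, that of TBL41, named after its values were seen, with a log2 change of -0.87 ± 0.17, and a median of -0.37 (camera adjusted p = 9.6e-05; adjusted p = 0.513 with an estimated correlation). Xyloglucan endotransglucosylases had 1 fall among 6, XTH19, and a median of -0.74 (camera adjusted p = 0.0175; adjusted p = 0.513 with an estimated correlation). Without potassium-starved root replicate 1, the camera adjusted p of extensins was 0.0985, and without control root replicate 1 that of the xyloglucan endotransglucosylases was 0.0510.

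None of 59 cytosolic ribosomal protein genes passed on its own in potassium-starved roots, but the family as a set lay below other genes. It had a median of -0.28 on the log2 scale (camera adjusted p = 2.0e-06; adjusted p = 0.625 with an estimated correlation). Mitochondrion-encoded genes lay higher, 11 of 12 with a positive change and a median of 0.37, with 0 past the threshold. Camera gave an adjusted p of 0.00282 (adjusted p = 0.513 with an estimated correlation), which was 0.143 without control root replicate 2. Plastid-encoded genes, dim in roots, had a median of 0.25 with 0 of 53 past the threshold (camera adjusted p = 0.0468; adjusted p = 0.778 with an estimated correlation). That call was lost after quantile normalization (0.0826), without control root replicates 1 (0.112) and 2 (0.995) and without potassium-starved root replicates 1 (0.0649) and 2 (0.357).

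**Figure D2:**
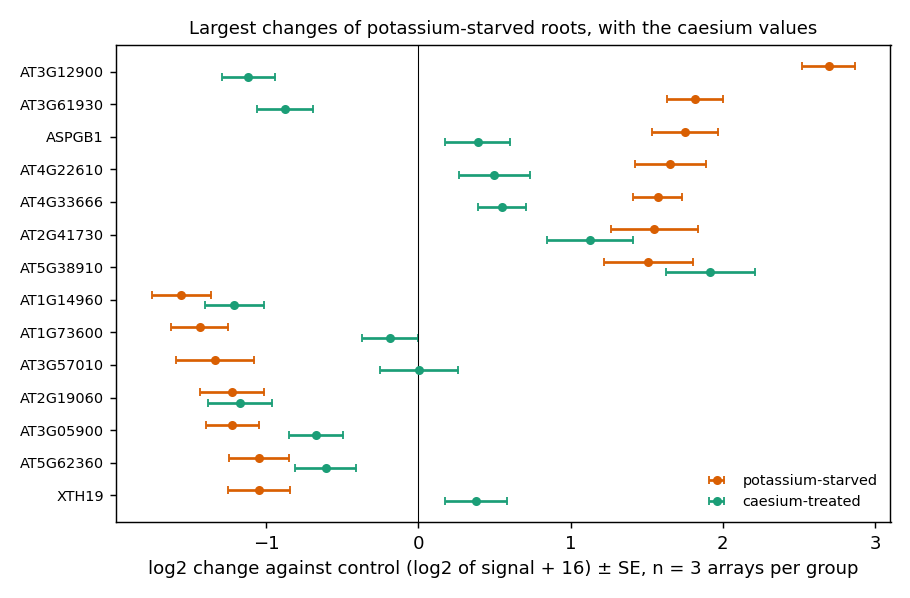
Log2 change against control roots (horizontal axis, log2 of signal + 16) of the 7 largest rises and 7 largest falls of potassium-starved roots, in orange, with the caesium values of the same genes in green. Points are limma estimates with SE from 3 arrays per group; AT3G12900 stood at 2.70 under potassium starvation and at -1.12 under caesium.

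In total, 200 of 13647 probe sets changed in potassium-starved roots, 133 up and 67 down, and 93 by 2-fold or more; with each array centred on its median 162 rose and 46 fell. The scanner background averaged 65.3 ± 7.48 in potassium-starved roots against 77.0 ± 1.89 in control roots (SD, n = 3; two-sided exact permutation p = 0.1, the smallest the design allows). With that background as a covariate 1 probe set passed, and with array weights 1133 did, 540 up and 593 down, so that falls outnumbered rises. Of 15 named genes 7 passed in all 6 fits without 1 array; AT2G41730, AT5G38910, AT3G57010, AT2G19060, AT3G05900, AT5G62360, XTH19 and EXPA4 did not (adjusted p up to 0.171). The count was 85 without control root replicate 1, 116 without control root replicate 2, 48 without potassium-starved root replicate 2 and 40 without replicate 3 of the same group. With settings chosen after seeing the data it was 62 with the 25S ribosomal RNA signal as a covariate and 128 without the 2 root arrays titled as repeats.

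Caesium raised AT3G13610 in shoots, listed with the synonym F6'H1 and an enzyme of coumarin synthesis. Its signal rose from 12.9 ± 10.1 in control shoots to 142 ± 60.7 in caesium-treated shoots (SD, n = 3), a log2 change of 2.44 ± 0.33 at a limma adjusted p of 0.0118. The control mean lay below the floor of 26.7, so the size depends on the pseudocount: it was 3.78 with 1, where the adjusted p was 0.0533, and 1.39 with 64. AT1G26380 rose from 24.8 ± 9.46, also below the floor, to 114 ± 19.7 (log2 change 1.69 ± 0.23) and AT1G43910 from 62.0 ± 9.65 to 232 ± 45.4 (1.66 ± 0.20), each at an adjusted p of 0.0118. The largest fall was that of MSRB6, a methionine sulfoxide reductase, from 206 ± 34.8 to 51.4 ± 13.2 (SD, n = 3; log2 change -1.72 ± 0.29, adjusted p = 0.0289). That of AT5G12050 was from 441 ± 200 to 125 ± 56.2 (-1.68 ± 0.32, adjusted p = 0.0415).

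AT2G41730 (log2 change 1.76 ± 0.33), AT1G65690 (1.72 ± 0.29), AT1G68620 (1.66 ± 0.31) and AT5G38900 (1.66 ± 0.31) also rose in caesium-treated shoots, with adjusted p between 0.0289 and 0.0397, AT1G65690 from a control mean below the floor. BZIP61 (-1.58 ± 0.25), AT5G03120 (-1.40 ± 0.24), the auxin response repressor IAA29 (-1.31 ± 0.21), AT2G43550 (-1.17 ± 0.21) and COR15B (-1.06 ± 0.22) fell, with adjusted p between 0.0197 and 0.0498. Among genes of oxidative stress, 2 of 5 rose and 3 of 5 adjusted over the list alone. NDB2 rose from 77.5 ± 9.48 to 185 ± 44.6 (SD, n = 3; log2 change 1.09 ± 0.21, adjusted p = 0.0424). GR1, a glutathione reductase, rose from 209 ± 8.00 to 417 ± 67.1 (0.94 ± 0.19, adjusted p = 0.0483). Neither passed without any 1 array, with adjusted p of 0.0690 to 0.169 for NDB2 and 0.0651 to 0.194 for GR1, and 1 of the 5 rose without control shoot replicate 2 and 0 in the other 5 fits. Camera placed this list above other genes at an adjusted p of 0.00123, or an adjusted p = 0.506 with an estimated correlation. Of 3 senescence genes 1 rose, WRKY6 by 1.56 on the log2 scale (adjusted p = 0.0223; named after its values were seen), and 3 of 3 rose adjusted over the list alone; without 1 array, 1 rose without control shoot replicate 1 or 2 and 0 otherwise. Of 4 genes of the abscisic acid, drought and cold response 1 fell, COR15B, and 3 fell adjusted over the list alone. None of 5 photosynthesis genes passed, over all probe sets or adjusted over the list alone, and of 4 cell wall expansion genes 0 passed over all probe sets and 1 fell adjusted over the list alone.

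Further families differed from other genes as sets in caesium-treated shoots. RALF-like peptides, secreted signals of growth, had a median of -0.58 over 6 members, all with a negative change (camera adjusted p = 0.00508; adjusted p = 0.739 with an estimated correlation). RNA polymerase subunits had 0 of 9 past the threshold and a median of 0.38 (camera adjusted p = 0.0379; adjusted p = 0.739 with an estimated correlation). Mitochondrion-encoded genes had 0 of 12 past the threshold and a median of 0.27 (camera adjusted p = 0.0379; adjusted p = 0.760 with an estimated correlation). WRKY factors had 1 rise among 5 and a median of 0.41 (camera adjusted p = 0.0392; adjusted p = 0.739 with an estimated correlation). Cytochromes P450 passed only with the replicate number as a block (adjusted p = 0.0293, against 0.0831 without it and adjusted p = 0.739 with an estimated correlation). After quantile normalization the camera adjusted p was 0.0727 for the WRKY factors and 0.0691 for the mitochondrion-encoded genes. For these families in turn it was 0.0565 and 0.133 without control shoot replicate 2, 0.0628 and 0.0612 without control shoot replicate 3, and 0.104 and 0.529 without caesium-treated shoot replicate 1. It was 0.0947 for the WRKY factors without caesium-treated shoot replicate 2, and for the RNA polymerase subunits 0.213 without control shoot replicate 2 and 0.142 without caesium-treated shoot replicate 1.

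Altogether 136 of 13647 probe sets changed in caesium-treated shoots, 104 up and 32 down, and 104 by 2-fold or more; 790 changed with the replicate number as a block, which pairs these samples. The split was 64 up and 57 down with each array centred on its median, and 116 up and 62 down after quantile normalization. The count was 0 without caesium-treated shoot replicate 3, 3 without replicate 2 and 65 without replicate 1 of that group, 2 without control shoot replicate 3 and 70 without control shoot replicate 1. It was also 0 by a linear model without moderation and 50 with a pseudocount of 1, but 670 with all 18 arrays in 1 fit and 1330 with array weights. None of the 16 named genes passed in all 6 fits without 1 array, where adjusted p reached 0.194, and MSRB6, NDB2 and GR1 passed in 0 of them. The fits and counts without 1 array left out the pairing, so they show how far the unpaired model depends on single arrays.

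In caesium-treated roots no probe set passed limma's test at an adjusted p under 0.05, and the named genes below passed only under alternatives. PDF1.4, a plant defensin, had a signal of 38.4 ± 7.05 in control roots and 86.4 ± 8.49 in caesium-treated roots (SD, n = 3), a log2 difference of 0.92 ± 0.14. AT5G38910 stood at 38.3 ± 14.2 and 193 ± 79.0 (1.92 ± 0.29), and AT1G78780 at 35.8 ± 8.36 and 120 ± 31.4 (1.38 ± 0.22). AT3G12900 stood at 139 ± 39.9 and 53.9 ± 4.61 (-1.12 ± 0.17), and AT5G48430 at 826 ± 96 and 404 ± 79.1 (-1.01 ± 0.16). Each of these 5 had an adjusted p of 0.0628, the smallest of the comparison. With the replicate number as a block, which pairs these samples, all 5 passed: the adjusted p was 0.0306 for PDF1.4, 0.0113 for AT5G38910, 0.0310 for AT1G78780, 0.0314 for AT3G12900 and 0.0363 for AT5G48430.

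Gene families differed from other genes as sets in caesium-treated roots, although no member passed. Cytosolic ribosomal protein genes had a median of 0.23 over 59 members (camera adjusted p = 2.1e-08, and adjusted p = 0.832 with an estimated correlation). The camera adjusted p was 0.0150 without caesium-treated root replicate 1. Mean log2 values of the family overlapped, at 0.49, -0.021 and 0.29 on the caesium-treated and 0.12, 0.067 and -0.14 on the control arrays. Defensins and other cysteine-rich peptides had a median of 0.47 over 6 members, 5 of them with a positive change (camera adjusted p = 0.00117; adjusted p = 0.182 with an estimated correlation). Plastid-encoded genes had a median of 0.28 over 53 members (camera adjusted p = 0.00485; adjusted p = 0.861 with an estimated correlation). Nuclear genes of photosynthesis lay higher beside them, with means in control and caesium-treated roots of 66.6 and 147 for RCA and 55.6 and 103 for LHCB4.1. Means were 16.1 and 31.5 for SBPASE, 17 and 30.2 for PRK and 2.47 and 22.3 for LHCB4.2, mostly below the floor of 27.7. RCA and LHCB4.1, the 2 tested, did not pass over all probe sets and were higher adjusted over the list alone. Extensins had a median of -0.43 over 9 members (camera adjusted p = 0.0428; adjusted p = 0.725 with an estimated correlation; 0.0646 with the replicate number as a block). The trichome birefringence-like family had a median of -0.18 over 16 (camera adjusted p = 0.0253; adjusted p = 0.725 with an estimated correlation). The camera adjusted p of extensins was 0.101 without control root replicate 1, 0.168 without control root replicate 2, 0.210 without caesium-treated root replicate 1 and 0.123 without replicate 2 of that group. For the trichome birefringence-like family it was 0.110 and 0.168 without control root replicates 1 and 2, and 0.0561 and 0.201 without caesium-treated root replicates 2 and 3. For plastid-encoded genes it was 0.0736 and 0.934 without control root replicates 1 and 2, and 0.0561 without caesium-treated root replicate 2.

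Beside the 0 calls, 1352 of 13647 probe sets had an unadjusted p under 0.05 where 682 would do so by chance, 2 passed by a linear model without moderation, and 51 passed with the replicate number as a block, which pairs these samples. With array weights 22 passed, and 27 with all 18 arrays in 1 fit. The count was 13 without control root replicate 2, 2 without caesium-treated root replicate 2 and 1 without replicate 3 of that group. The scanner background averaged 67.5 ± 4.55 in caesium-treated against 77.0 ± 1.89 in control roots (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible), and 0 probe sets passed with it as a covariate. The signal of the 25S ribosomal RNA control probe set was 1754 ± 1378 in caesium-treated roots and 463 ± 334 in control roots (SD, n = 3; two-sided exact permutation p = 0.4), with 2862, 2188 and 212 on the single caesium arrays.

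Set against each other directly, shoots of caesium-treated plants had far less of AT4G18280, CML41 and AMY1, which potassium starvation had raised. AT4G18280 was at 1497 ± 346 in potassium-starved and 52.4 ± 7.21 in caesium-treated shoots (SD, n = 3), a log2 difference of -4.45 ± 0.19 at a limma adjusted p of 1.6e-06. AT1G58420 (-3.74 ± 0.20), CML41 (-3.68 ± 0.31), COR15A (-3.38 ± 0.57), SAL2 (-3.36 ± 0.37) and AMY1 (-3.28 ± 0.25) were also lower, with adjusted p up to 0.00328. Plastid-encoded genes were higher with caesium, led by rpl22 (2.51 ± 0.50), psaA (2.43 ± 0.40), rpl14 (2.31 ± 0.52) and ndhH (2.22 ± 0.45, from a potassium-starved mean below the floor), beside the nuclear genes AT2G16660 (2.21 ± 0.28) and Cpn60beta2 (2.2 ± 0.25), a chaperonin subunit of the chloroplast. The signal of psaA was 330 ± 229 in potassium-starved, 1590 ± 258 in caesium-treated and 1381 ± 363 in control shoots (SD, n = 3).

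Of 67 plastid-encoded genes 23 were higher and 1 lower in caesium-treated than in potassium-starved shoots, with atpF at 1.77 ± 0.26 (camera adjusted p = 0.0181; adjusted p = 0.612 with an estimated correlation). Calmodulin-like genes were lower, 3 of 5, with CML38 at -2.08 ± 0.35 beside CML41. So were 4 of 10 ubiquitin-conjugating enzymes, with UBC29 at -0.71 ± 0.16 and UBC30 at -0.63 ± 0.17, and 3 of 8 autophagy genes, with ATG8D at -1.20 ± 0.18 and ATG8G at -0.49 ± 0.14. Each of these 3 families had a camera adjusted p of 0.0181, and an adjusted p = 0.612 with an estimated correlation. RALF-like peptides had 3 of 6 lower, with RALFL22 at -1.19 ± 0.21 and RALFL33 at -0.99 ± 0.24 (camera adjusted p = 0.0224; adjusted p = 0.612 with an estimated correlation; 0.0531 after quantile normalization). Tetraspanins, membrane scaffold proteins, had 2 of 7 lower, TET9 at -2.01 ± 0.23, to a mean below the floor, and TET8 at -0.72 ± 0.23 (camera adjusted p = 0.0353; adjusted p = 0.612 with an estimated correlation; 0.0531 after quantile normalization). Without potassium-starved shoot replicate 2 the camera adjusted p was 0.132 for the RALF-like peptides and 0.0967 for each of the other 5 families. It was 0.0973 for tetraspanins without caesium-treated shoot replicate 2 and 0.0597 for plastid-encoded genes without replicate 1 of that group.

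Among lists fixed before the data were examined, 3 of 4 genes of the abscisic acid, drought and cold response were lower with caesium, also adjusted over the list alone: COR15A, LTI30 (-2.69 ± 0.44) and COR47 (-1.43 ± 0.21). Cell wall expansion had 2 of 4 lower, and 3 of 4 adjusted over the list alone, with EXLA1 at -2.33 ± 0.32 and XTH19 at -1.82 ± 0.25. Oxidative stress genes went both ways, with NDB2 at -1.23 ± 0.21 and AT2G21640 at 0.75 ± 0.25 (adjusted p = 0.0456), and the counts of 1 higher and 1 lower among 5 held adjusted over the list alone. In total 3885 of 13647 probe sets differed, 2558 higher and 1327 lower with caesium, and 1122 by 2-fold or more. The median difference of all probe sets was 0.13 on the log2 scale, and relative to it the split was 1577 higher and 2105 lower with each array centred on its median and 1943 and 1633 after quantile normalization. Of 28 named genes 24 passed in all 6 fits without 1 array, which left out the pairing by replicate number. AT2G21640, TET8, UBC30 and ATG8G did not (limma adjusted p up to 0.154). Without caesium-treated shoot replicates 1, 2 and 3 in turn the count was 2102, 2576 and 2411, without potassium-starved shoot replicate 2 it was 2261, and without moderation it was 2537.

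Roots under the same 2 treatments differed most in AT3G12900, at 965 ± 36.7 in potassium-starved and 53.9 ± 4.61 in caesium-treated roots (SD, n = 3). This was a log2 difference of -3.81 ± 0.17 at a limma adjusted p of 2.0e-06. AT3G61930 (-2.69 ± 0.18), AT5G19700 (-2.60 ± 0.23), AT1G73120 (-2.50 ± 0.26), AT5G48430 (-2.04 ± 0.16) and AT4G16000 (-2.0 ± 0.47) were also lower with caesium, with adjusted p up to 0.0369. The caesium-treated means of AT5G19700 and AT4G16000 lay below the floor, and AT4G16000 had an adjusted p of 0.0528 with a pseudocount of 1 and 0.0570 with 64. BGLU25, a beta-glucosidase, was higher, at 763 ± 262 against 175 ± 89.2 (log2 difference 2.06 ± 0.48, adjusted p = 0.0348). So were AT5G10130 (1.84 ± 0.27), AT4G12490 (1.68 ± 0.28), AT5G14650 (1.60 ± 0.38), the glutathione transferase GSTU25 (1.54 ± 0.33) and AT5G01870 (1.54 ± 0.35), with adjusted p between 0.00653 and 0.0403. XTH19 was higher by 1.42 ± 0.20 (adjusted p = 0.00579) and EXPA4 lower, at -0.62 ± 0.15 (adjusted p = 0.0436), 1 higher and 1 lower among 6 cell wall expansion genes. Adjusted over the list alone, 4 were higher and 1 lower.

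Cytosolic ribosomal protein genes were the family with the most members past the threshold in roots of caesium-treated against potassium-starved plants. Of 59 genes 13 were higher and 0 lower, 36 were higher adjusted over the list alone, and 58 had a positive difference. AT5G22440 stood at 1038 ± 266 against 504 ± 54.3 (SD, n = 3; log2 difference 0.99 ± 0.20, adjusted p = 0.0241) and AT3G04920 at 866 ± 172 against 468 ± 71.3 (0.85 ± 0.17, adjusted p = 0.0229). The family median was 0.49 on the log2 scale (camera adjusted p = 6.4e-16; adjusted p = 0.681 with an estimated correlation). Mean log2 values of the family, relative to all root arrays, were 0.49, -0.021 and 0.29 on the caesium-treated arrays, -0.34, -0.20 and -0.27 on the potassium-starved arrays and 0.12, 0.067 and -0.14 on the control arrays. The caesium array with the lowest of these had a 25S signal of 2188, and the highest one had 2862. Autophagy genes had 1 of 8 lower and a median of -0.28 (camera adjusted p = 0.0285; adjusted p = 0.681 with an estimated correlation). The call was lost after quantile normalization (0.0513) and without caesium-treated root replicate 1 (0.156) or potassium-starved root replicate 2 (0.107).

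**Figure D3:**
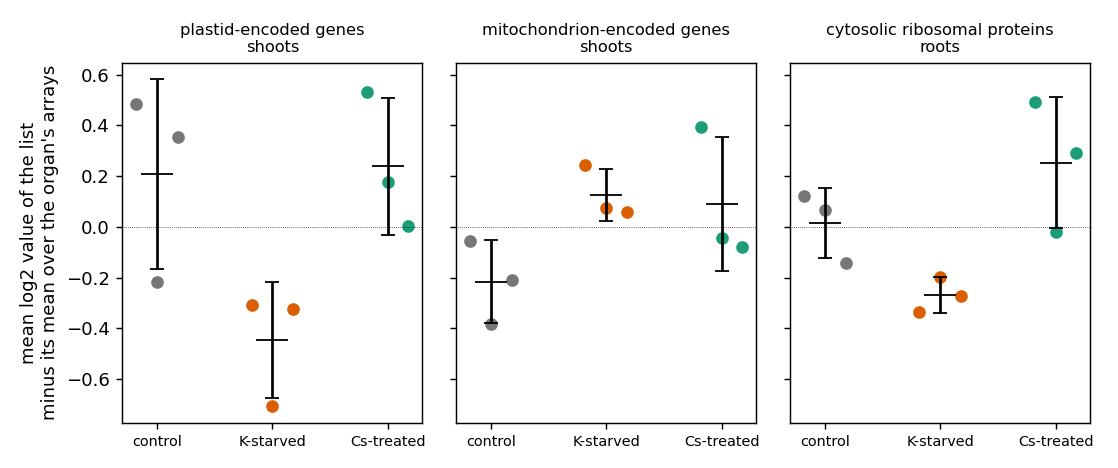
Mean log2 value of a gene family on each array minus its mean over the arrays of the organ (vertical axis, log2), for plastid-encoded and mitochondrion-encoded genes in shoots and cytosolic ribosomal protein genes in roots, with the mean and SD of 3 arrays per group. The ribosomal scores of the potassium-starved roots lay between -0.34 and -0.20, below all caesium-treated roots.

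By count, 690 of 13647 probe sets differed between roots of caesium-treated and potassium-starved plants, 341 higher and 349 lower with caesium, and 204 by 2-fold or more; with each array centred on its median the split was 273 and 492. The count was 149 without potassium-starved root replicate 2, 151 without replicate 3 of that group, 149 without caesium-treated root replicate 1 and 208 without caesium-treated root replicate 3. It was 331 with the scanner background as a covariate 63 without moderation and 2539 with array weights. Of 16 named genes 8 passed in all 6 fits without 1 array; BGLU25, GSTU25, AT5G01870, AT3G04920 and AT5G22440 passed in some, and AT5G14650, AT4G16000 and EXPA4 in 0 (adjusted p up to 0.140). With settings chosen after seeing the data it was 377 without the 2 arrays titled as repeats, 21 with the 25S signal as a covariate, 1 higher and 20 lower, and 13 without the 2 caesium-treated arrays with a high 25S signal, all lower.

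**Figure D4:**
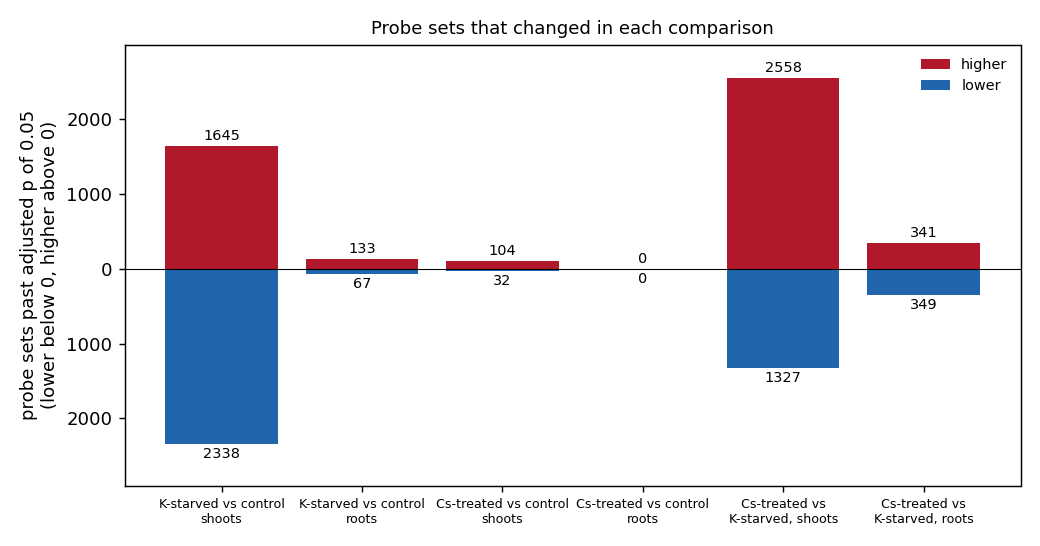
Number of probe sets past an adjusted p of 0.05 in each comparison, higher above 0 in red and lower below 0 in blue, by limma with 3 arrays per group. The bars run from 0 in caesium-treated roots to 1645 higher and 2338 lower in potassium-starved shoots.

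Shoot responses to caesium and potassium starvation had a covariance above that simulated for shared control arrays alone. The signs of the called probe sets could not be weighed in this way. The simulated groups held no real change and no pairing by replicate number, while potassium starvation changed 3983 probe sets. Of the 136 probe sets called under caesium, 120 had the same sign under potassium starvation. In 100 simulations of unchanged groups with the same controls, as many probe sets with the strongest changes gave a mean of 124 (116 to 131). Under both treatments 81 rose, against 68.2 simulated (54 to 79) and 12.5 for independent lists, and 22 fell, against 25.05 simulated (20 to 30) and 5.48, while 1 went opposite ways. AT3G13610, at 12.9 ± 10.1 in control shoots, stood at 291 ± 61.4 under potassium starvation and 142 ± 60.7 under caesium (SD, n = 3). AT1G43910 stood at 373 ± 81.1 and 232 ± 45.4, and BZIP61 at 8.37 ± 7.49 and 31.1 ± 13.5. Across probe sets the log2 changes correlated with r = 0.476 and had a covariance of 0.114, against a simulated 0.0333. The simulated r had a mean of 0.501 over 100 sets of unchanged groups. It is no mark for the observed r, since real changes under 1 treatment alone would lower it. Both comparisons used the same 3 control arrays, which were too few to split into sets of at least 2 each. With separate pairs of a treated and a control array, chosen after the result was seen, the covariance averaged 0.104 over 6 ways. This argues against the shared controls as the whole source, though part of the covariance may come from them. In the same direction went 103 probe sets, 540 with the replicate number as a block, 59 without control shoot replicate 1 and 2 without control shoot replicate 3.

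In roots the log2 changes of the treatments correlated across probe sets with r = 0.200 and had a covariance of 0.0177 against a simulated 0.0231. The simulated r of 0.501 is for unchanged, unpaired groups and is no mark for the observed r, as in shoots. No probe set was called under both treatments, 13 were with the replicate number as a block, and 5 without control root replicate 2. The pairing rule did not hold for potassium starvation against control in roots, so the block is no paired result there. AT3G12900 went apart, at 965 ± 36.7 under potassium starvation, 53.9 ± 4.61 under caesium and 139 ± 39.9 in control roots (SD, n = 3).

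The response to potassium starvation differed between the organs in 1187 of 11867 probe sets by limma's interaction test, 580 with a higher and 607 with a lower response in roots, and 687 by 2-fold or more. For both treatments, higher and lower refer to the log2 response in roots minus that in shoots, with its sign. A fall in shoots alone therefore counts as a higher response in roots. CML41 went from 39.1 ± 17.7 to 1122 ± 217 in shoots and from 28.0 ± 7.40 to 40.5 ± 5.00 in roots (SD, n = 3), a difference of the log2 responses of -4.03 ± 0.36 at an adjusted p of 9.5e-06. XTH19 rose in shoots and fell in roots, a difference of -2.92 ± 0.34 at an adjusted p of 4.8e-05. AT2G32190 (-3.55 ± 0.53), SAL2 (-3.54 ± 0.42), AT1G55210 (-3.50 ± 0.26), AT1G57630 (-3.21 ± 0.63) and AT5G52390 (-3.16 ± 0.46) also had lower responses in roots, with adjusted p up to 0.00417. Responses were higher in roots in this signed sense for AT2G16660 (2.92 ± 0.34), psaA (2.65 ± 0.57), AT4G33666 (2.18 ± 0.26), AT4G23820 (2.05 ± 0.32), AT5G12050 (1.96 ± 0.36) and atpF (1.96 ± 0.46), with adjusted p up to 0.0122. Of these, psaA, AT4G23820, AT5G12050 and atpF had fallen in shoots, so their positive differences do not mean larger changes in roots. AT4G33666 rose in roots, from 96.5 ± 21.5 to 316 ± 22.9, and stood at 482 ± 51.8 in control and 317 ± 74.2 in potassium-starved shoots.

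Among oxidative stress genes, NDB2 (-2.2 ± 0.25) and ATMDAR2 (-0.91 ± 0.27) responded less in roots, 2 of 4 measured in both organs and 3 adjusted over the list alone. Of 19 named genes 17 passed in all 12 fits without 1 array, and ATMDAR2 (5 fits) and AT4G25740 (11 fits) did not (adjusted p up to 0.104). Among cell wall expansion genes 2 of 4 had a lower signed response in roots, with EXLA1 at -2.10 ± 0.39, while 1 had a higher one. These counts did not change adjusted over the list alone. Cytosolic ribosomal protein genes had lower responses in roots, 6 of 59 past the threshold, with AT4G25740 at -0.96 ± 0.24 and AT2G19740 at -0.78 ± 0.19 and a median of -0.39 (camera adjusted p = 3.4e-08; adjusted p = 0.778 with an estimated correlation). Plastid-encoded genes had higher signed responses in roots, 8 of 53, with ndhA at 1.77 ± 0.38 and a median of 0.66 (camera adjusted p = 1.9e-06, and adjusted p = 0.778 with an estimated correlation). As a set they had fallen in shoots, and none passed in roots. The count of probe sets was 1897 with array weights. Without potassium-starved root replicate 3 it was 744, and it was 747 without the 2 arrays titled as repeats, a setting chosen after seeing the data. Of the probe sets tested in both organs, 59 rose and 26 fell under potassium starvation in both, where 13.0 and 5.77 would for independent lists, and 6 went opposite ways.

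The response to caesium differed between the organs in 21 of 11867 probe sets, 9 with a higher and 12 with a lower response in roots, each by 2-fold or more. AT3G13610 had a lower response in roots: its signal was 1734 ± 216 in control and 1696 ± 210 in caesium-treated roots but rose in shoots from below the floor (SD, n = 3), a difference of -2.48 ± 0.38 at a limma adjusted p of 0.0175, or 0.0644 with a pseudocount of 1. AT2G25450 (-2.09 ± 0.34), AT4G01870 (-1.57 ± 0.28) and AT2G28710 (-1.24 ± 0.24) also had lower responses in roots. AT4G33666 (1.45 ± 0.26), AT4G30650 (1.38 ± 0.27), AT3G62630 (1.24 ± 0.23), the plastid-encoded ndhC (1.19 ± 0.23), AT3G20790 (1.06 ± 0.21) and AT5G51010 (1.04 ± 0.20) had higher ones. All 9 had an adjusted p between 0.0266 and 0.0417. RALF-like peptides had a median difference of 0.79 over 5 members (camera adjusted p = 0.00885; adjusted p = 0.613 with an estimated correlation). Plastid-encoded genes had one of 0.27 over 53 (camera adjusted p = 0.00885; adjusted p = 0.613 with an estimated correlation; 0.298 after quantile normalization). Cytosolic ribosomal protein genes had a median difference of 0.18 over 59 (camera adjusted p = 0.00885; adjusted p = 0.656 with an estimated correlation), but after quantile normalization the direction turned and the adjusted p was 0.908. WRKY factors, with a median difference of -0.54 over 5, passed only with the replicate number as a block (adjusted p = 0.0226, against 0.0581 without it and adjusted p = 0.613 with an estimated correlation). Leaving out 1 array brought the camera adjusted p over 0.05 for the ribosomal proteins (control shoot replicates 2 and 3, 0.208 and 0.0542; caesium-treated shoot replicate 3, 0.166; control root replicate 3, 0.360; caesium-treated root replicate 1, 0.448). It did so for RALF-like peptides without control shoot replicate 2 (0.0551) or 3 (0.0542), and for plastid-encoded genes without control shoot replicate 1 (0.127) or 3 (0.0570), caesium-treated shoot replicate 3 (0.133) or control root replicate 2 (0.296).

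The split was 8 higher and 6 lower with each array centred on its median and 5 and 11 after quantile normalization. Without caesium-treated shoot replicate 2 or 3 the count was 1, and without control shoot replicate 3 it was 3. Without control root replicates 1, 2 and 3 in turn it was 5, 10 and 7, and without caesium-treated root replicates 1, 2 and 3 in turn it was 7, 5 and 8. It was 6 with a pseudocount of 1, 12 with a filter at the 60th percentile, 6 with the scanner background as a covariate and 0 without moderation, but 165 with the replicate number as a block and 296 with array weights. None of the 10 named genes passed in all 12 fits without 1 array, where adjusted p reached 0.156: AT3G13610 passed in 10, AT3G62630 in 0. Among settings chosen after seeing the data it was 6 with the 25S signal as a covariate, 2 without the arrays titled as repeats and 1 without the caesium-treated root arrays with a high 25S signal.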

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

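Tests of scaling, of the 25S ribosomal RNA signal, of the arrays titled as repeats, of poly(A) capture, of RNA degradation, of separate pairs of treated and control arrays and of leaving out 1 control array were chosen only after the result was seen.

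Responses that differed between roots and shoots by a test of the difference itself comprised 1187 probe sets for potassium starvation and 21 for caesium. Under potassium starvation the log2 response in roots minus that in shoots was 2.92 for AT2G16660, 2.65 for psaA, 2.18 for AT4G33666, 2.05 for AT4G23820, 1.96 for AT5G12050, 1.96 for atpF and 1.77 for ndhA. It was -4.03 for CML41, -3.55 for AT2G32190, -3.54 for SAL2, -3.50 for AT1G55210, -3.21 for AT1G57630, -3.16 for AT5G52390 and -2.92 for XTH19. For NDB2 it was -2.2, for EXLA1 -2.10, for AT4G25740 -0.96, for ATMDAR2 -0.91 and for AT2G19740 -0.78. Under caesium it was 1.45 for AT4G33666, 1.38 for AT4G30650, 1.24 for AT3G62630, 1.19 for ndhC, 1.06 for AT3G20790 and 1.04 for AT5G51010. It was -2.48 for AT3G13610, -2.09 for AT2G25450, -1.57 for AT4G01870 and -1.24 for AT2G28710.

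Families whose response differed between the organs by camera had medians of -0.386 for cytosolic ribosomal proteins and 0.659 for plastid-encoded genes under potassium starvation. Under caesium the medians were 0.182 for cytosolic ribosomal proteins, 0.786 for RALF-like peptides and 0.265 for plastid-encoded genes. With an estimated correlation the adjusted p of these 5 calls lay between 0.613 and 0.778. The 25S ribosomal RNA control probe set, which the comparisons do not use, had a mean signal of 1754 in caesium-treated roots, above the 463 of control roots (two-sided exact permutation p = 0.4).

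Cytosolic ribosomal protein transcripts were higher in caesium-treated than in potassium-starved roots, with a difference of the mean log2 value of the family of 0.523 between 3 and 3 arrays. Scaling between arrays and the arrays titled as repeats were argued against as the whole cause: the difference was 0.465 ± 0.153 (SE) with each array centred on its median and 0.626 ± 0.124 without the 2 arrays. Carry-over of ribosomal RNA into the labelled target was not decided. With the 25S signal as a covariate the difference was 0.494 ± 0.199 (SE), little below the 0.523 without it. With 3 against 3 arrays and a covariate, a value so little past 2 SE is not told apart from 0. With this covariate 21 of the 690 probe sets of the whole comparison passed. A lower output of ribosomal protein transcripts under potassium starvation, a higher one under caesium, or both may underlie the difference. This stays a hypothesis found and tested on the same arrays, and carry-over stays open beside it.

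Plastid-encoded transcripts were lower in potassium-starved than in control shoots, by -0.653 in the mean log2 value of the family. Less capture of the transcripts of both organelles, which lack stable poly(A) tails, was argued against only for a loss of equal size in both. Mitochondrion-encoded transcripts did not fall but stood higher by 0.341 ± 0.154 (SE). With 3 against 3 arrays a rise so little past 2 SE is not told apart from 0, so a smaller loss stays open. The camera adjusted p of the mitochondrion-encoded genes was 0.107 without control shoot replicate 2 and 0.0537 without potassium-starved shoot replicate 2. A lower capture of plastid transcripts alone was not tested, since mitochondrial transcripts cannot show it. Scaling was argued against too, as the difference was -0.535 ± 0.212 with each array centred on its median. RNA degradation was not decided: the mean log2 ratio of 3 prime to 5 prime control probe sets differed by -0.0857 ± 0.095. This lies within its error of 0, so it showed no rise and does not exclude a small one. The ubiquitin ratio alone was lower, 1.33 ± 0.105 against 1.74 ± 0.216 (SD, n = 3; two-sided exact permutation p = 0.1, the smallest the design allows), away from degradation, while the actin and GAPDH ratios differed by 0.00289 and 0.108. A lower level of plastid transcripts in potassium-starved shoots may be a response of the plant. This stays open with degradation, with a smaller loss of both organelles' transcripts and with a lower capture of plastid transcripts alone.

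The log2 changes of shoots under caesium and potassium starvation had a covariance of 0.114 across probe sets, with r = 0.476. Of the 136 probe sets called under caesium, 120 had the same sign under potassium starvation. Simulations of unchanged groups with the same controls gave a mean of 124 (116 to 131). Those simulations held no real change and no pairing, so the signs do not decide on a shared direction. Shared control arrays were argued against as the whole source: with each treated array set against the control of its own number and no array used for both treatments, the covariance ranged from 0.0679 to 0.157 over 6 ways. With separate controls regardless of number, the covariance ranged from 0.0225 to 0.113. Those ways part arrays that the numbers pair, which may lower the covariance. Whether it did so was not tested, so the low end of this range leaves a part for the shared controls open. A single control array out of place was argued against as the whole source. With separate pairs the covariance was 0.110, 0.131 and 0.0711 without replicate numbers 1, 2 and 3, where the treated arrays of that number were left out with the control. With the same controls for both treatments and only control shoot replicate 1, 2 or 3 left out, it was 0.128, 0.165 and 0.101. The count of probe sets in the same direction, however, fell from 103 to 2 without control shoot replicate 3. A response common to caesium and to lack of potassium may account for it, which stays a hypothesis: no value here measures the uptake or content of potassium.

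With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Of these, 1 gave as many calls in each of 5 comparisons, the real one. The real count and the highest of the other splits were 3983 and 0 for potassium starvation in shoots, 200 and 84 in roots, and 136 and 1 for caesium in shoots. They were 3885 and 0 for caesium against potassium starvation in shoots and 690 and 0 in roots. For caesium in roots all 10 splits gave at least the real count of 0, and the highest was 4. In the comparisons whose replicate numbers pair the samples, the other 3 splits that part all pairs gave 0 calls, and the splits with a call put both arrays of a pair together.

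Among 100 splits, the real one included, 7 gave at least the real 1187 probe sets for the difference of the responses to potassium starvation. The real split is counted in these 7, a share that does not exclude chance. The highest other split had 3273, several times the real count, which points to a structure of the arrays: all 7 kept the real shoot groups, and so the shoot response itself, and the highest without these was 6. For caesium 4 of 100, the real one counted among them, were as large as the real 21, a share under 0.05, and the highest other was 71. These 4 were among the 7 splits that kept the real shoot groups, and the highest without them was 2. Since splits with the real shoot groups keep the shoot response and the others remove it, neither share decides whether a difference between the organs arose by chance.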

How the results depend on the processing

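Only the 25S covariate, the lack of the 2 root arrays titled as repeats and the lack of the 2 caesium-treated root arrays with a high 25S signal were chosen after the result was seen. Comparisons are named below as potassium (against control), caesium (against control) and direct (caesium-treated against potassium-starved), and the differences between organs as interactions. Over 156 gene results there were 3617 values under alternatives: 2999 kept direction and side of the threshold, 598 kept the direction without passing, 20 passed only then and 0 reversed. Of 36 camera calls 26 held after quantile normalization, 35 with the replicate block and 0 with an estimated correlation, and 189 of 246 held with 1 array left out. Cytosolic ribosomal proteins reversed in the caesium interaction after quantile normalization, at an adjusted p of 0.908. Dim probe sets limit what could be seen, since the floor lay at a signal of 26.7 in shoots and 27.7 in roots. An arm left with 2 arrays or 1 was assumed to vary like the others. Where no cause is given, the cause was not tested.

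A pseudocount of 1 gave 130 for potassium roots, 50 for caesium shoots and 6 for the caesium interaction. No filter, which tests more probe sets, gave 93, 30 and, for caesium roots, 1. The filter at the 60th percentile gave 12 for the caesium interaction. The replicate block gave 724 for potassium roots, with 343 up and 381 down where the majority had risen, 790 and 51 for caesium shoots and roots, 1629 for direct roots, 2125 and 165 for the potassium and caesium interactions, and 540 and 13 in the same direction in shoots and roots. All 18 arrays gave 670 and 27 for caesium shoots and roots, and only the 2 groups, which leaves fewer arrays, 75 for potassium roots. Array weights gave 1133 for potassium roots, 1330 and 22 for caesium shoots and roots, 2539 for direct roots and 1897 and 296 for the interactions. The scanner background gave 1 for potassium roots, 206 for caesium shoots, 331 for direct roots and 6 for the caesium interaction. No moderation gave 23 for potassium roots, 0 and 2 for caesium shoots and roots, 2537 and 63 for direct shoots and roots, and 0 for the caesium interaction. The 25S covariate gave 62 for potassium roots, 21 for direct roots and 6 for the caesium interaction. Without the arrays titled as repeats there were 128 for potassium, 1 for caesium and 377 for direct roots, and 747 and 2 for the interactions. Without the caesium-treated root arrays with a high 25S signal, which leaves 1 caesium array, there were 13 for direct roots and 1 for the caesium interaction. A 2-fold minimum, a stricter threshold, gave 1480 and 93 for potassium shoots and roots, 1122 and 204 for direct shoots and roots and 687 for the potassium interaction. A threshold of 0.1, a looser one, gave 511 for potassium roots, 446 and 30 for caesium shoots and roots, 1699 for direct roots, 2025 and 71 for the interactions, and 318 and 11 in the same direction in shoots and roots.

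With each array left out in turn the counts ran from 2372 to 3808 for potassium shoots, 40 to 238 for potassium roots, 0 to 121 for caesium shoots, 0 to 13 for caesium roots, 2102 to 3659 for direct shoots and 149 to 623 for direct roots. They ran from 744 to 1580 and from 1 to 30 for the potassium and caesium interactions, and from 2 to 104 and 0 to 5 in the same direction in shoots and roots.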

Other observations

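The comparisons and the set test in this part were planned, but its genes were chosen only after their values were seen. In potassium-starved roots PDF2.1, PDF1.4 and LCR69 rose, 3 of 6 measured defensins and other cysteine-rich peptides, a family listed after the probe table was seen, whose set test did not pass there (camera adjusted p = 0.0704). PDF2.1 went from a signal of 164.7 ± 25.9 in control roots to 436.8 ± 54.4 in potassium-starved roots and 328.1 ± 21.2 in caesium-treated roots (SD, n = 3). Its log2 change under potassium starvation was 1.33 ± 0.15 at a limma adjusted p of 0.00399. PDF1.4 rose by 0.94 ± 0.14 (limma adjusted p = 0.0104) and LCR69 by 0.85 ± 0.18 (limma adjusted p = 0.0462). LCR69 passed in 0 of 6 fits without 1 array (up to 0.166) and PDF1.4 did not without potassium-starved root replicate 3 (0.0613), while PDF2.5 and LCR68 had log2 differences of -0.63 and -0.59 that did not pass. Under caesium the values of PDF2.1, PDF1.4 and LCR69 were 0.94, 0.92 and 0.60, none past the threshold, but with the replicate number as a block PDF2.1 (adjusted p = 0.0310) and PDF1.4 (0.0306) passed.

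In shoots, GRX480, a glutaredoxin of the salicylate response, rose under both treatments, by 2.14 ± 0.25 with potassium starvation and 1.25 ± 0.25 with caesium (limma adjusted p = 0.000282 and 0.0424). Under caesium GRX480 passed only without control shoot replicate 1 among the 6 fits without 1 array (up to 0.169 otherwise). THI2.1, a thionin of the jasmonate response, rose by 1.94 ± 0.60 with potassium starvation (limma adjusted p = 0.0337), from 34.7 ± 12.1 to 247 ± 252 (SD, n = 3), with 65.0, 535 and 141 on the single arrays. Without potassium-starved shoot replicate 2 the change was 1.18 (adjusted p = 0.107), and it passed only without replicate 1 of that group. THI2.1 had a log2 difference of 0.57 ± 0.60 with caesium that did not pass. AT3G13610 rose by 3.46 ± 0.33 in potassium-starved shoots and by 0.95 ± 0.15 in potassium-starved roots, where its signal went from 1734 ± 216 to 3368 ± 292 (SD, n = 3; adjusted p = 0.0649 without potassium-starved root replicate 2). AT1G53540, a small heat shock protein, rose in potassium-starved roots by 1.46 ± 0.20 (limma adjusted p = 0.0073), from 15.5 ± 7.33 to 70.8 ± 19.4, and stood at 17.5 ± 4.18 in caesium-treated roots (SD, n = 3). AT1G60160, of the potassium transporter list, stood at 112 ± 46.5 in control and 72.2 ± 12.0 in potassium-starved shoots and did not pass, except with the replicate number as a block (adjusted p = 0.0489). The root hair marker AT3G49960 had means of 89.2 ± 105, 24.9 ± 7.95 and 87.3 ± 49.8 in control, potassium-starved and caesium-treated roots (SD, n = 3), the first from 31.5, 210 and 25.7 on the single arrays, with a log2 difference of -0.92 ± 0.55 under potassium starvation that did not pass.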
